A study of Mus musculus with 6 samples.

How the data were processed

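Small RNA libraries of primary articular chondrocytes from ICR mice were compared between 2 groups of 3 libraries, passage 0 (P0, called the control in the labels) and passage 2 (P2, cells carried through serial passages in normoxia). Per the labels' protocols, the cells were kept in medium with serum at 20% O2, RNA was taken as total RNA with TRI reagent, and libraries were made with the TruSeq small RNA kit. The labels number the replicates 1 to 3 in each group and do not say whether they came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

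The deposited files, 1 per sample, hold raw read counts per mature miRNA arm, as whole numbers with no normalization, per the file headers and values. A file lists only miRNAs with at least 1 read, and a miRNA absent from a sample's file was taken as 0. Per the submitters' processing notes, bcl2fastq 1.8.4, cutadapt and bedtools were used with the mouse build mm10, with no role or order. The aligner, the miRNA annotation release and the treatment of reads that match several miRNAs are not given in the sources used here. The counts themselves bear on the last point: 13 pairs of miRNAs with at least 100 reads had counts within 5% of each other in all 6 libraries, and all 13 were related by name, among them miR-199a-3p and miR-199b-3p, miR-486a-5p and miR-486b-5p, and miR-467a-5p and miR-467b-5p. The counts of miR-467a-5p and miR-467b-5p were the same, as were those of miR-669a-5p and miR-669p-5p, so these members shared their reads. The mean reads, log2 fold changes and SE of miR-669a-3p and miR-669o-3p were also equal, as those of members that share their reads would be. Whether reads were counted for both members of the remaining pairs was not tested. Such pairs are reported as uncertain and are not taken as separate measurements.

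Totals per library ran from 17996986 to 23467689 reads, and each listed 965 to 1007 miRNAs. A floor of 3 reads corresponded to 0.128 to 0.167 CPM. Reads of small RNA libraries without molecular identifiers are not independent molecules, so floors cover counting error only.

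Of 1258 miRNAs listed in any library, 575 passed edgeR's filterByExpr and were tested, and they held at least 99.99% of the reads of each library. The test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3, robust glmQLFit with TMM factors, P2 against P0, no covariate), with Benjamini-Hochberg adjustment and a threshold of 0.05. The estimated common biological coefficient of variation was 16.1%. CPM in the text are TMM-normalised CPM as mean ± SD over 3 libraries, log2 fold changes are the fitted values of P2 over P0, and the standard error (SE) is the absolute log2 fold change divided by the square root of F. In the text, a miRNA "rose" or "fell" where its adjusted p from this test was under 0.05. Single values per library, the share of reads in the 10 most abundant miRNAs and the number detected at 1 CPM, were compared by two-sided exact permutation tests, for which 3 against 3 libraries cannot give a p below 0.1.

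miRNA lists were written before the data were examined. They cover cartilage (miRNAs enriched in cartilage or chondrocytes, or regulated by SOX9), senescence and p53, hypoxia, inflammation, fibroblasts and contractile cells, and the imprinted Dlk1-Dio3 region. They also cover the miR-17-92, let-7, miR-29, miR-30, miR-15/16 with miR-322-450, miR-23/27/24 and miR-181 families, the multicopy Sfmbt2 miRNAs, and markers of muscle, blood, endothelial, epithelial and neural cells. A miRNA belonged to a list by its name without arm and copy number. The 17 lists with 3 or more tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over those lists, and again with an estimated correlation. The senescence list included miR-204, which the group behind this design is known to have followed, so that miRNA and its list are not independent evidence. The list was tested again without miR-204 and the miR-29 family, an alternative added after the data were seen.

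The named miRNAs follow a rule fixed before the data were examined. It takes the 10 with the largest rise and the 10 with the largest fall among those past the threshold, with non-overlapping groups and a mean of at least 10 CPM, the 5 most abundant that rose and the 5 most abundant that fell, a fixed set (miR-140, miR-455, miR-204-5p, miR-34a-5p, miR-210-3p, miR-146a-5p and miR-21a-5p), the 5 most abundant miRNAs of either group, and up to 4 members of each list by mean CPM. The rule did not say which CPM. TMM-normalised CPM were used, which leaves out miR-138-5p. Its log2 fold change of −1.57 would place it among the 10 largest falls, but its mean lay just below 10 CPM. Other miRNAs are named as members of a list, of a count of 5 or fewer, or of a genomic cluster, and were chosen after their values were seen.

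Hairpin positions and overlapping genes came from the GENCODE M21 annotation of GRCm38, the assembly that mm10 names, with positions counted from 1. Of the tested miRNAs, 549 matched an annotated hairpin and 506 matched a single locus. For 176 hairpins with both arms tested, the log2 ratio of 5p to 3p counts was compared between groups with limma. Hairpins of miRNAs that matched a single locus, within 10 kb on 1 strand, were joined into clusters. The log2 fold changes of a hairpin's arms were averaged. The spread of these hairpin means within clusters was set against 10000 shuffles of the cluster labels.

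The steps were tested on simulated data. In simulated counts for this comparison, with 200 of 575 miRNAs changed, the test recovered 37.9% of changes of 1.5-fold, 87.7% of 2-fold and 100% of 4-fold, and 2% of its calls were false. A list changed in a simulation of 575 miRNAs was called and 0 of 16 other lists were, all by camera. The simulated miRNAs were drawn independently, while estimated correlations within the real lists reached 0.359. This simulation therefore does not test camera's false calls among correlated members. In a simulation of 176 hairpins, 19 of 20 ratios changed 3-fold were recovered, with 2 false calls.

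Libraries of 1 group were compared before averaging. Pearson correlations of log2 CPM, across miRNAs with a mean of at least 10 CPM by library totals, ran from 0.9925 to 0.9961 within groups. Count differences exceeded sampling noise in every pair, with a chi-square of at least 310 per degree of freedom, so no pair differed by sampling noise alone. This does not show that the libraries came from separate cultures. Alternatives tried were other scalings (DESeq2's size factors, upper quartile, library totals, and totals without the 10 most abundant miRNAs), other filters, DESeq2 1.42.0, limma-voom, a fold threshold, counts summed per stem, the replicate number as a block, each library left out in turn, and other splits of the libraries. After the data were seen, an alternative with 1 miRNA per set linked by such pairs was added. Figures were drawn with matplotlib 3.10.9.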

Results

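Small RNA was sequenced from primary mouse articular chondrocytes at passage 0 (P0, 3 libraries) and after serial passaging under normoxia to passage 2 (P2, 3 libraries). The P0 libraries held 17996986, 23276938 and 20987495 miRNA reads and the P2 libraries 23467689, 22447393 and 23408735. The comparison asks how prolonged exposure to normoxia in culture changes the miRNAs of these cells, and passage number and time in normoxia change together in it. Values are TMM-normalised CPM, mean ± SD with n = 3 per group, and adjusted p-values are from edgeR's quasi-likelihood test unless another test is named.

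After passaging, miR-204-5p rose from 6.46 ± 1.11 to 111 ± 28.4 CPM, a log2 fold change of 4.11 (SE 0.22, adjusted p = 8.12e-08). The contractile-cell miRNAs miR-143-3p and miR-145a-3p, the p53 target miR-34b-5p and the growth-associated miR-21a-5p also rose. So did 5 of 6 tested arms of the miR-29 family, which targets collagen mRNAs. Log2 fold changes were 1.12 to 1.70 among miR-143-3p, miR-145a-3p, miR-29c-3p, miR-29b-3p, miR-29a-3p, miR-34b-5p and miR-21a-5p. Among miRNAs with a mean of at least 10 CPM, the largest fall was that of miR-130b-3p, from 161 ± 15.2 to 43.9 ± 6.37 CPM (log2 fold change −1.88, SE 0.15, adjusted p = 2.05e-06), and members of the proliferation-linked miR-17-92 cluster and of the imprinted Dlk1-Dio3 region fell too. The cartilage-enriched miR-140-3p fell moderately from 57530 ± 4130 to 41339 ± 3237 CPM, while its partner arm miR-140-5p was at 2716 ± 791 and 2810 ± 432 CPM.

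Of 575 miRNAs tested, 108 rose and 122 fell (47% and 53% of the calls), and 40 and 41 of these differed by more than 2-fold. The CPM of the groups did not overlap for 106 of those that rose and 121 of those that fell. Over all tested miRNAs, 52.0% had non-overlapping groups, against 10% by chance. With library totals as the only scaling, the counts were 77 and 175 (30.6% and 69.4%), and with totals that left out the 10 most abundant miRNAs they were 92 and 150 (38.0% and 62.0%). These scalings moved the median log2 fold change of all miRNAs by −0.19 and −0.11 against TMM. The 10 most abundant miRNAs held 61.9% ± 0.765 of the reads at P0 and 63.1% ± 1.25 at P2 (two-sided exact permutation p = 0.3, n = 3 per group), and 506 ± 9.17 and 491 ± 8.89 miRNAs reached 1 CPM (two-sided exact permutation p = 0.2, n = 3 per group). The smallest p this design allows in these permutation tests is 0.1.

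**Figure D1:**
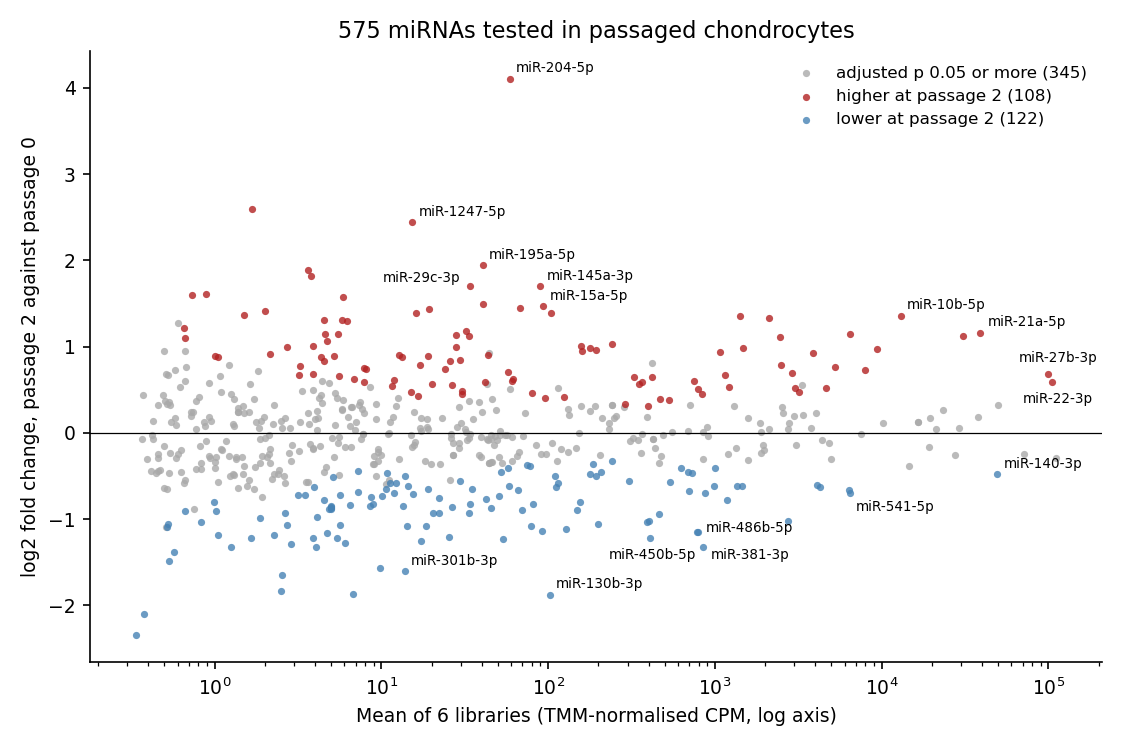
Log2 fold change of P2 against P0 (vertical axis) against the mean of the 6 libraries in TMM-normalised CPM (horizontal, log axis) for the 575 tested miRNAs. Red points are the 108 that rose, blue points the 122 that fell and grey points the 345 others, and miR-204-5p stands at 4.11.

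Principal components were taken over miRNAs with a mean of at least 10 CPM by library totals. The first held 78.0% of the variance of log2 CPM and separated the groups. On it, P0 replicates 1 and 2 lay at −6.83 and −6.85, P0 replicate 3, nearer to the P2 libraries, at −4.63, and the P2 libraries at 5.93 to 6.40. Without that library, 108 miRNAs rose and 113 fell, and 210 of the 230 calls were made again.

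Again among miRNAs with a mean of at least 10 CPM, the largest rises after miR-204-5p were those of miR-1247-5p (log2 fold change 2.44, SE 0.43), miR-195a-5p (1.94, SE 0.21), miR-29c-3p (1.70, SE 0.16), miR-145a-3p (1.70, SE 0.14), miR-34b-5p (1.49, SE 0.28), miR-15a-5p (1.47, SE 0.14), miR-145a-5p (1.45, SE 0.27), miR-24-1-5p (1.44, SE 0.16) and miR-29b-3p (1.39, SE 0.18). Their adjusted p-values ran from 2.05e-06 to 0.00380. After miR-130b-3p, the largest falls were those of miR-301b-3p (−1.60, SE 0.17), miR-381-3p (−1.32, SE 0.14), miR-675-3p (−1.25, SE 0.17), miR-20a-5p (−1.23, SE 0.17), miR-450b-5p (−1.22, SE 0.14), miR-18a-5p (−1.21, SE 0.18), miR-486b-5p and miR-486a-5p (both −1.15, SE 0.14) and miR-17-5p (−1.14, SE 0.16). Their adjusted p-values ran from 1.67e-05 to 1.32e-04. The miR-486a-5p and miR-486b-5p counts were nearly equal in every library and cannot be taken as separate measurements.

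Among abundant miRNAs, miR-22-3p rose from 83502 ± 2091 to 125464 ± 3267 CPM (log2 fold change 0.59, SE 0.13, adjusted p = 0.00342) and miR-27b-3p from 76187 ± 4240 to 121739 ± 14255 CPM (0.68, SE 0.15, adjusted p = 0.00231). miR-21a-5p rose from 23969 ± 1300 to 53655 ± 10918 CPM (1.16, SE 0.16, adjusted p = 1.06e-04) and miR-143-3p from 19428 ± 1520 to 42369 ± 8533 CPM (1.12, SE 0.16, adjusted p = 1.16e-04). miR-10b-5p rose from 7294 ± 3589 to 18707 ± 3487 CPM (1.36, SE 0.36, adjusted p = 0.0198), a call that ended with upper-quartile scaling (adjusted p = 0.0567), without a count filter (0.151), and without P0 replicate 2 (0.105), P2 replicate 1 (0.122) or P2 replicate 2 (0.129). The most abundant miRNAs that fell were miR-140-3p (−0.48, SE 0.14, adjusted p = 0.0134), miR-541-5p (−0.69, SE 0.19, adjusted p = 0.0102), miR-182-5p (−0.67, SE 0.16), miR-410-3p (−0.63, SE 0.12) and miR-322-3p (−0.61, SE 0.12). The call of miR-541-5p ended without P0 replicate 2 (adjusted p = 0.0536), P2 replicate 1 (0.0691) or P2 replicate 3 (0.0663). The most abundant miRNA at P0, miR-127-3p, was at 122639 ± 12571 and 99980 ± 14497 CPM (−0.29, SE 0.16, adjusted p = 0.154), and miR-148a-3p at 77274 ± 9754 and 65142 ± 2779 CPM (−0.25, SE 0.15, adjusted p = 0.195). For miR-181a-5p the values were 44265 ± 2632 and 55127 ± 10826 CPM (0.32, SE 0.16, adjusted p = 0.135).

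**Figure D2:**
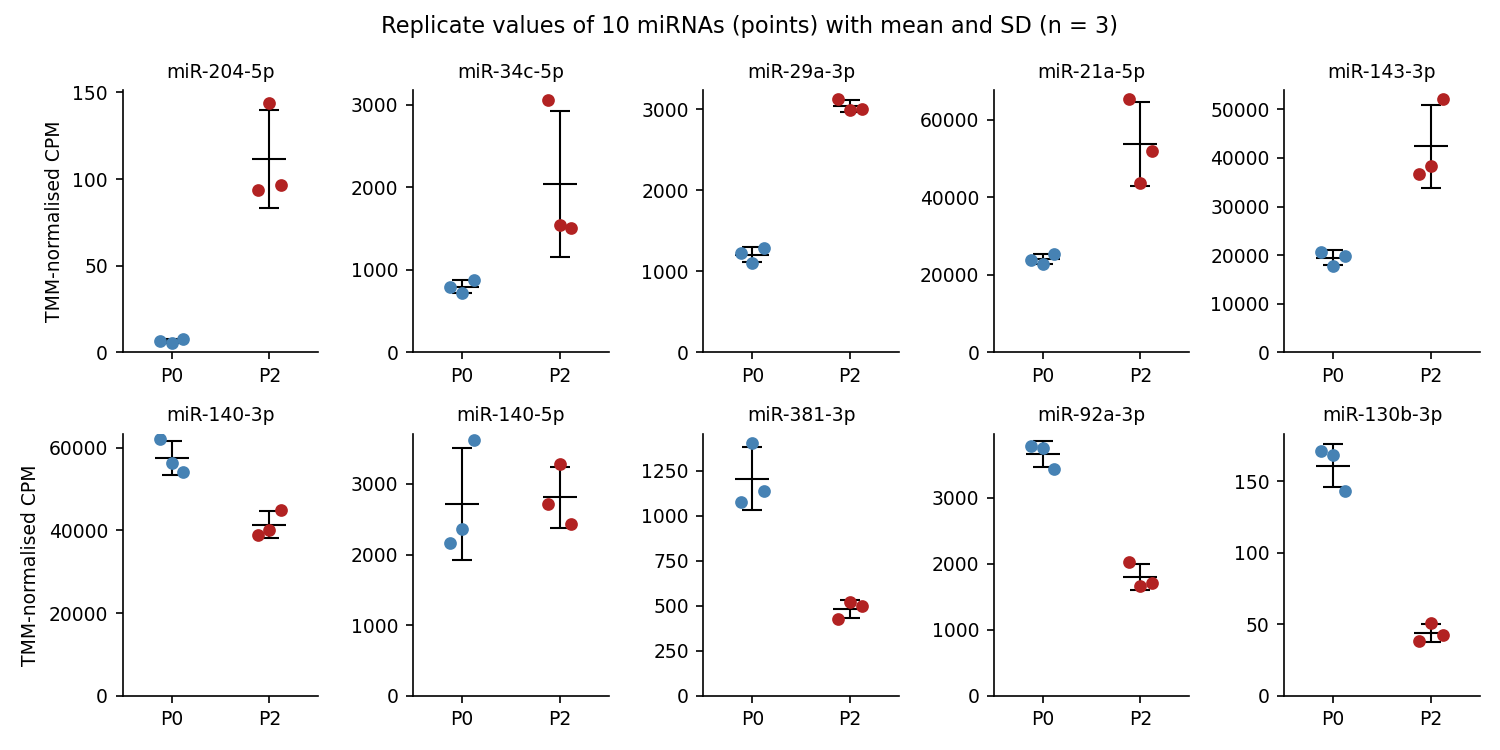
TMM-normalised CPM (vertical axes, linear from 0) of 10 miRNAs in each P0 library (blue) and P2 library (red), with horizontal bars for the mean and whiskers for the SD of 3 libraries. The miR-204-5p values lie at 5.52 to 7.68 CPM at P0 and 93.9 to 144 CPM at P2, while the groups overlap for miR-140-5p.

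The cartilage list, of miRNAs known as enriched in cartilage or chondrocytes or regulated by SOX9, went both ways. Of 17 tested, 5 rose, 4 fell and 8 did not pass, and the same counts held adjusted over the list alone. With library totals, 5 rose and 7 fell. Their median log2 fold change was 0.05 (camera adjusted p = 0.771, and adjusted p = 0.833 with an estimated correlation), and it turned to −0.14 with library totals and −0.06 with totals that left out the 10 most abundant miRNAs. Those that fell were both arms of miR-675, which is processed from H19 (−1.25 for 3p and −1.33 for 5p), miR-140-3p (−0.48) and miR-148a-5p (−0.47). miR-1247-5p (2.44), miR-1247-3p (1.89), miR-30a-5p (0.97), miR-30a-3p (0.65) and miR-193b-3p (0.62) rose. No arm of miR-140, miR-455 or miR-675 rose. Both arms of miR-455 were at −0.24 (SE 0.16 for 5p and 0.14 for 3p, adjusted p = 0.260 and 0.194), miR-140-5p at 0.05 (SE 0.19, adjusted p = 0.864) and miR-26a-5p at 0.18 (adjusted p = 0.365). The change in the ratio of miR-140-5p to miR-140-3p was 0.55 on the log2 scale (SE 0.27, limma adjusted p = 0.216).

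miRNAs associated with senescence and p53 were higher as a list. Of 23 tested, 15 rose and 8 did not pass, also adjusted over the list alone, with a median log2 fold change of 0.71 (camera adjusted p = 6.88e-08, and adjusted p = 0.181 with an estimated correlation). The list held miR-204, which was known to have been followed in this design, so its count is not independent evidence. The 4 arms of miR-34b and miR-34c, direct p53 targets, rose, with miR-34c-5p going from 795 ± 80.6 to 2039 ± 883 CPM (1.36, SE 0.29, adjusted p = 0.00820). That call ended without P0 replicate 1, where the log2 fold change was 1.36 with an SE of 0.40 (adjusted p = 0.0572). miR-34a-5p rose less, from 708 ± 81.2 to 971 ± 65.2 CPM (0.45, SE 0.13, adjusted p = 0.0104), a call that ended with library totals (adjusted p = 0.152), with totals that left out the 10 most abundant miRNAs (0.0594) and without P0 replicate 2 (0.0726). miR-192-5p (0.59), miR-194-5p (0.83) and both arms of miR-22 (0.59 and 0.71) rose, while miR-335-3p was at −0.02 (adjusted p = 0.947), miR-335-5p at 0.55 (adjusted p = 0.155) and miR-146a-5p at −0.28 (SE 0.23, adjusted p = 0.352). Without miR-204 and the miR-29 family, a set chosen after the data were seen, 9 of 16 rose and the median was 0.57 (camera adjusted p = 0.00663, and adjusted p = 0.313 with an estimated correlation).

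The miR-29 family rose in 5 of 6 tested arms, also adjusted over the list alone (median 1.36, camera adjusted p = 7.87e-06, and adjusted p = 0.199 with an estimated correlation). miR-29a-3p went from 1206 ± 91.6 to 3045 ± 76.6 CPM (1.34, SE 0.12, adjusted p = 6.85e-06), and its minor arm miR-29a-5p rose as well (1.30, SE 0.20). The minor arm miR-29c-5p, also among those that rose, was at only 0.437 CPM at P0 and 1.35 CPM at P2. miRNAs abundant in fibroblasts and contractile cells rose in 11 of 19, with 1 that fell, or 13 and 1 adjusted over the list alone (median 0.89, camera adjusted p = 1.05e-05, and adjusted p = 0.199 with an estimated correlation). Both arms of miR-143, miR-145a and miR-21a rose, and miR-221-3p rose from 886 to 1414 CPM (0.67, SE 0.16), whereas miR-199b-5p fell (−0.51, SE 0.13, adjusted p = 0.00830). That call ended without P2 replicate 3, where it was at −0.41 (SE 0.15, adjusted p = 0.0527). miR-199a-3p and miR-199b-3p, whose counts lay within 5% of each other in every library, were both at 0.12 (adjusted p = 0.535 and 0.531).

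The miR-23/27/24 clusters rose in 7 of 10, also adjusted over the list alone (median 0.62, camera adjusted p = 4.29e-04, and adjusted p = 0.313 with an estimated correlation), with miR-24-3p at 1.11 (SE 0.16), miR-23b-3p at 0.99 (SE 0.14) and miR-27a-3p at 0.11 (adjusted p = 0.535). The miR-30 family rose in 5 of 11, also adjusted over the list alone (median 0.31, camera adjusted p = 0.0219, and adjusted p = 0.462 with an estimated correlation), from 0.97 for miR-30a-5p and 0.52 for miR-30d-5p among those that rose to 0.01 for miR-30c-5p (adjusted p = 0.947) and 0.21 for miR-30e-5p (adjusted p = 0.273). With library totals, 2 members of the miR-30 family rose and its median was 0.12. With totals that left out the 10 most abundant miRNAs the median was 0.20. The miR-30 list's call ended with a filter of 10 CPM (adjusted p = 0.0925), with arms summed per stem (0.0892) and without P0 replicate 1 (0.0558), and that of miR-30d-5p with library totals (adjusted p = 0.0565). NF-kB-responsive and inflammatory miRNAs rose in 6 of 10, also adjusted over the list alone (median 0.69, camera adjusted p = 0.0199, and adjusted p = 0.350 with an estimated correlation). The inflammatory list's call ended with a filter of 10 CPM (adjusted p = 0.394) and with arms summed per stem (0.0892). In that list, miR-132-3p (1.12, SE 0.16) and miR-146b-5p (0.94, SE 0.27) rose while miR-146a-5p did not pass and miR-155-5p was at 0.02 (adjusted p = 0.935). The miR-146b-5p call ended without P0 replicate 2 (adjusted p = 0.0945) or P2 replicate 1 (0.0905).

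**Figure D3:**
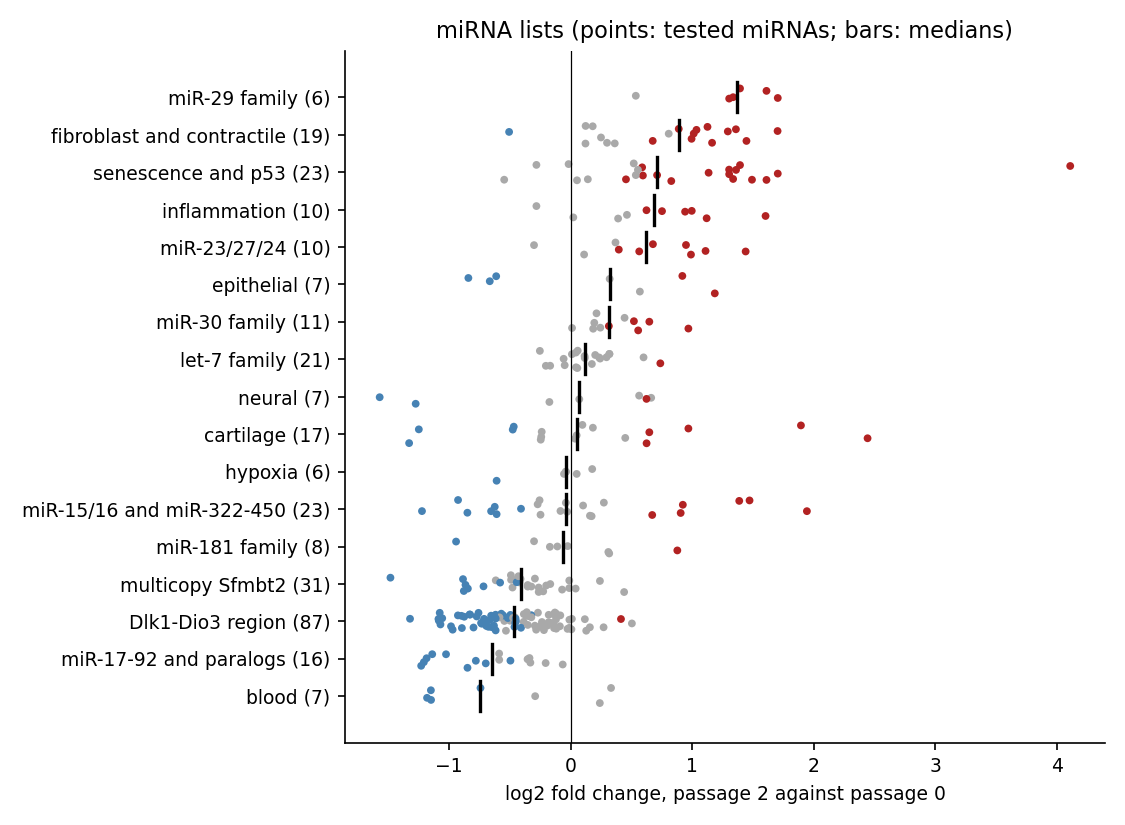
Log2 fold change of P2 against P0 (horizontal axis) of each tested miRNA, by list, with the number tested in parentheses and a black bar at the list's median. Red points rose, blue points fell and grey points did not pass, and medians run from −0.74 for blood markers to 1.36 for the miR-29 family, with those of the cartilage, let-7 and neural lists changing sign when library totals, with or without the 10 most abundant miRNAs, are the scaling.

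The miR-17-92 cluster and its paralogs, which are driven by MYC and E2F and linked to cell cycle entry, fell in 9 of 16, or 11 adjusted over the list alone (median −0.64, camera adjusted p = 2.40e-04, and adjusted p = 0.313 with an estimated correlation). miR-92a-3p went from 3656 ± 196 to 1796 ± 198 CPM (−1.03, SE 0.13, adjusted p = 4.99e-05) and miR-25-3p from 1492 ± 392 to 869 ± 123 CPM (−0.78, SE 0.18, adjusted p = 0.00486). miR-93-5p was at −0.35 (adjusted p = 0.0588). miR-19b-3p, at −0.33 (SE 0.63, adjusted p = 0.724), varied widely at P0 (126 ± 95.7 CPM), and its value was 0.47 without P0 replicate 3.

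miRNAs of the imprinted Dlk1-Dio3 region fell in 43 of 87, with 1 that rose, or 44 and 1 adjusted over the list alone (median −0.46, camera adjusted p = 6.88e-08, and adjusted p = 0.313 with an estimated correlation). The fall was largest for miR-381-3p, from 1204 ± 176 to 482 ± 48.1 CPM, and miR-433-3p (−1.06, SE 0.12) and miR-410-3p (−0.63) also fell. The one that rose was miR-668-3p (0.41, SE 0.14, adjusted p = 0.0273). It was named after its value was seen. Its call ended with library totals (adjusted p = 0.226), with totals that left out the 10 most abundant miRNAs (0.106) and without P0 replicate 1 (0.0520), P0 replicate 3 (0.108) or P2 replicate 2 (0.167). With upper-quartile factors 2 members rose and 37 fell, while 56 fell with library totals (median −0.66) and 50 with totals that left out the 10 most abundant miRNAs (median −0.58). Of the most abundant members, miR-127-3p, miR-411-5p (−0.39, adjusted p = 0.0581) and miR-136-3p (−0.12, adjusted p = 0.535) did not pass. By position, 89 tested miRNAs had their single locus between 109563692 and 109747960 on chromosome 12, and 81 of them had a negative log2 fold change. Mir1247, which lies beyond that span in the Dio3 opposite-strand transcript (110278048 to 110278129), is not in the list. Both of its arms rose (2.44 and 1.89).

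**Figure D4:**
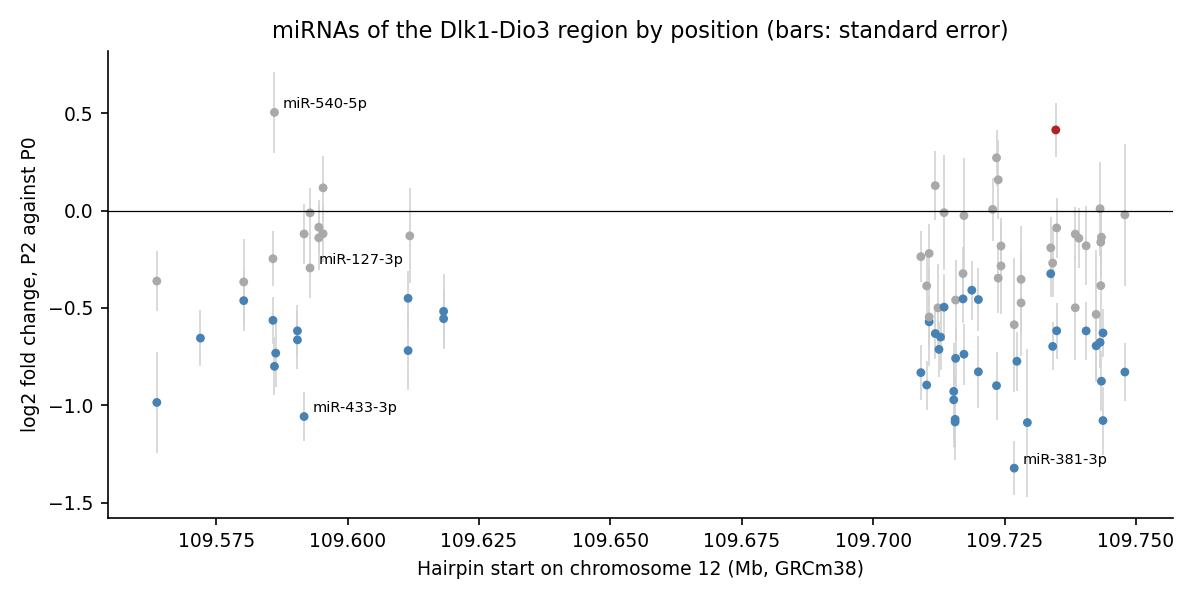
Log2 fold change of P2 against P0 with its standard error (vertical axis and bars) by hairpin start on chromosome 12 of GRCm38 (horizontal axis, Mb), for 89 miRNAs with a single locus in the Dlk1-Dio3 region. Blue points are the 44 that fell, the red point the 1 that rose, and grey points did not pass, while Mir1247, at 110278048 and with both arms higher, lies outside the plotted span.

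The list of the miR-15/16 seed family and the X-linked miR-322-450 cluster moved both ways. Of 23, 6 rose, 7 fell and 10 did not pass, also adjusted over the list alone, and the median of −0.04 and the camera direction, which was upward, differed in sign (camera adjusted p = 0.905, and adjusted p = 0.959 with an estimated correlation). With library totals the median was −0.23, and with totals that left out the 10 most abundant miRNAs it was −0.15, with 5 that rose and 9 that fell in both. With TMM, those that rose were miR-195a-5p (1.94), miR-15a-5p (1.47), miR-497a-5p (1.39), miR-16-5p (0.92, from 2692 ± 236 to 5101 ± 559 CPM), miR-15b-5p (0.90) and miR-195a-3p (0.67), and those that fell all came from miR-322, miR-351, miR-450a, miR-450b and miR-503. In that cluster miR-450a-5p was at −0.41 (adjusted p = 0.0136), a call that ended without P0 replicate 2 (0.0562), P2 replicate 1 (0.0717) or P2 replicate 3 (0.0507), and miR-351-5p at −0.26 (adjusted p = 0.311). The miR-195a-3p call ended with library totals (adjusted p = 0.124), with totals that left out the 10 most abundant miRNAs (0.0756) and without P0 replicate 1 (0.111), P0 replicate 2 (0.0737), P2 replicate 2 (0.0937) or P2 replicate 3 (0.143).

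Hypoxia-responsive miRNAs were not detectably different as a list. miR-210-3p was at 2089 ± 193 CPM at P0 and 2161 ± 80.6 CPM at P2 (0.05, SE 0.12, adjusted p = 0.786), miR-103-3p at 0.18 (adjusted p = 0.278) and miR-322-5p at −0.04 (adjusted p = 0.815). Of the 6 tested, 1 fell, miR-322-3p, also adjusted over the list alone (median −0.04, camera adjusted p = 0.821, and adjusted p = 0.924 with an estimated correlation). The hypoxia median was −0.23 with library totals and −0.16 with totals that left out the 10 most abundant miRNAs. In the let-7 family, 1 of 21 rose, let-7c-1-3p (0.74, SE 0.17), named after its value was seen, also adjusted over the list alone. The let-7 median was 0.11 (camera adjusted p = 0.461, and adjusted p = 0.493 with an estimated correlation), −0.08 with library totals, where 1 rose and 2 fell, and just below 0 with totals that left out the 10 most abundant miRNAs. let-7f-5p (0.05), let-7a-5p (0.04), let-7c-5p (0.17) and let-7i-5p (−0.17) did not pass (adjusted p = 0.308 to 0.836). In the miR-181 family, 1 of 8 rose and 1 fell, also adjusted over the list alone (median −0.07, camera adjusted p = 0.905, and adjusted p = 0.959 with an estimated correlation). With library totals 1 rose and 3 fell (median −0.27), and with totals that left out the 10 most abundant miRNAs 1 and 2 (median −0.18). With TMM both calls came from miR-181c, whose 5p arm fell (−0.94, SE 0.13) and whose 3p arm rose (0.88, SE 0.19), while miR-181b-5p was at −0.30 (adjusted p = 0.107) and miR-181a-1-3p at −0.17 (adjusted p = 0.300).

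Markers of blood, muscle, endothelial, epithelial and neural cells were included as lists of other cell types. Of the 7 tested blood markers 4 fell, also adjusted over the list alone (median −0.74, camera adjusted p = 0.0330, and adjusted p = 0.313 with an estimated correlation), and all 4 were arms of miR-486, which is also made in muscle. The leukocyte and erythroid markers miR-142a-5p, miR-451a and miR-150-5p held 6 to 21 reads per library and did not pass. The call of the blood list ended with 1 miRNA per near-identical set (3 of 6 fell, adjusted p = 0.176), with arms summed per stem (0.158) and without P0 replicate 1 (0.0558) or P2 replicate 1 (0.0552). The 2 tested muscle markers, miR-133a-3p (0.48, adjusted p = 0.146) and miR-1a-3p (0.58, adjusted p = 0.123), were at 2.80 and 0.748 CPM at P0, and the endothelial miR-126a-3p and miR-126a-5p were at 0.08 and 0.03 (adjusted p = 0.736 and 0.932). Epithelial markers went both ways, with 2 of 7 that rose and 3 that fell, also adjusted over the list alone (median 0.32, camera adjusted p = 0.934, and adjusted p = 0.962 with an estimated correlation): miR-203-3p (1.19) and miR-141-3p (0.92) rose, miR-182-5p (−0.67), miR-183-5p (−0.61) and miR-183-3p (−0.84) fell, and miR-96-5p was at 0.57 (adjusted p = 0.202). The epithelial median was 0.13 with library totals, where 1 rose and 3 fell, and 0.21 with totals that left out the 10 most abundant miRNAs. The miR-141-3p call ended with library totals (adjusted p = 0.0541) and without P0 replicate 2 (0.0728). The call of miR-183-5p ended without P0 replicate 2 (adjusted p = 0.0505), P0 replicate 3 (0.0832), P2 replicate 1 (0.0691) or P2 replicate 2 (0.0888). Of the 7 neural markers, miR-9-5p rose (0.62, SE 0.17, adjusted p = 0.0103), miR-138-5p (−1.57, SE 0.19) and miR-153-3p (−1.27, SE 0.17) fell, also adjusted over the list alone, and miR-128-3p was at 0.07 (adjusted p = 0.758). The neural median of 0.07 differed in sign from the camera direction (adjusted p = 0.671, and adjusted p = 0.833 with an estimated correlation) and was −0.13 with library totals and −0.05 with totals that left out the 10 most abundant miRNAs, and the miR-9-5p call ended with library totals (adjusted p = 0.0799) and without P0 replicate 2 (0.0537).

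Multicopy miRNAs of the Sfmbt2 cluster, many of which have near-identical copies, fell in 8 of 31, or 7 adjusted over the list alone (median −0.41, camera adjusted p = 0.0202, and adjusted p = 0.446 with an estimated correlation). Of the 8, miR-466a-3p, miR-466b-3p, miR-466c-3p and miR-466e-3p (−0.85 to −0.89) had linked, nearly equal counts and are not separate measurements. With 1 miRNA per near-identical set, chosen after the data were seen, 5 of 25 fell and the list's call ended (camera adjusted p = 0.0521). Of all 31, 17 fell with library totals. With totals that left out the 10 most abundant miRNAs, 12 fell. miR-467a-5p and miR-467b-5p had the same counts and were at −0.35 (adjusted p = 0.0673), and miR-669a-5p and miR-669p-5p likewise at −0.26 (adjusted p = 0.189). The list's call ended with a filter of 10 CPM (adjusted p = 0.377) and without P2 replicate 2 (0.0599). In all, 10 of the 17 lists passed camera's test with the preset correlation, 8 with 1 miRNA per near-identical set, and 0 with an estimated correlation, where 3 had an unadjusted p under 0.05.

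In GRCm38, the Mir204 hairpin lies on chromosome 19 from 22750605 to 22750672 in an intron of Trpm3. Mir140 lies on chromosome 8 from 107551244 to 107551313 and overlaps annotated exon sequence of Wwp2, and Mir455 on chromosome 4 from 63256851 to 63256932 in an intron of Col27a1. Mir675 lies on chromosome 7 from 142577064 to 142577147 in an exon of H19, Mir1247 on chromosome 12 from 110278048 to 110278129 in an exon of Dio3os, and Mir21a on chromosome 11 from 86584067 to 86584158 in annotated exon sequence of Vmp1. Mir301b and Mir130b lie together on chromosome 16 between 17124061 and 17124496. Mir145a (61647825 to 61647894) and Mir143 (61649196 to 61649258) are neighbours on chromosome 18, outside other annotated genes.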

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

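All alternatives were chosen before the data were examined, except 1 miRNA per near-identical set (107 higher, 114 lower and 8 lists) and the reduced senescence list (10 lists). Beside 108 higher, 122 lower and 10 lists, DESeq2's size factors gave 112, 115 and 10, upper-quartile factors 110, 113 and 10, no filter 114, 124 and 10, DESeq2 105 and 105, and limma-voom 106 and 121. A mean of 10 CPM or more gave 70, 79 and 6, a fold threshold of 1.5 gave 40 and 36, and counts summed per stem gave 68, 79 and 7; fewer miRNAs are tested in the first and last, and the threshold asks for more than a difference. An estimated correlation left 0 lists. The share of the top 10 miRNAs differed by 1.13 percentage points (P2 minus P0) and that of the top 5 by −0.365; the cause was not tested. With the replicate number as a replicate block, 108, 122 and 10 were called and 217 of 230 calls were shared in the same direction, and the same-number correlations of deviations (−0.102, 0.518 and −0.120) do not pair the samples, nor did every library correlate best with its own number. The miR-10b-5p call was not among those shared (log2 fold change 1.46, edgeR adjusted p = 0.116 with the block). Leaving out 1 library gave 82 to 109 higher, 101 to 113 lower and 8 to 10 lists, with the fewest miRNAs without P0 replicate 2 and the fewest lists without P0 replicate 1, and 179 to 210 of the 230 calls were made again, with 0 of opposite sign. Changes under 1.5-fold are at the limit of this depth and replication, as the simulated recovery of 37.9% shows.

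No called list or called named miRNA changed sign under these alternatives. Uncalled ones that did are given next, and the cause was not tested unless the scaling shift itself (−0.195 for totals, −0.113 for totals without the top 10) covers it. With library totals the log2 fold changes were −0.145 (miR-140-5p), −0.149 (miR-210-3p), −0.0114 (miR-26a-5p), −0.0175 (miR-103-3p), −0.143 (let-7f-5p), −0.155 (let-7a-5p), −0.0246 (let-7c-5p), −0.0785 (miR-199b-3p), −0.0798 (miR-199a-3p), −0.182 (miR-30c-5p), −0.0901 (miR-27a-3p), −0.176 (miR-155-5p), −0.177 (miR-126a-5p), −0.113 (miR-126a-3p) and −0.129 (miR-128-3p). With totals without the top 10 they were −0.0585 (miR-140-5p), −0.0682 (miR-210-3p), −0.0597 (let-7f-5p), −0.0759 (let-7a-5p), −0.102 (miR-30c-5p), −0.00513 (miR-27a-3p), −0.0914 (miR-155-5p), −0.0866 (miR-126a-5p), −0.0296 (miR-126a-3p) and −0.0485 (miR-128-3p). miR-335-3p was 0.00425 with DESeq2's size factors, 0.00345 with upper-quartile factors and 0.00425 with DESeq2. The 10 CPM filter gave −0.0217 (miR-30c-5p), −0.0124 (miR-155-5p) and −0.00169 (miR-126a-5p), the replicate block −0.00326 (miR-155-5p) and −0.0110 (miR-126a-5p), and limma-voom −0.00929 and −0.0176 for the same pair. Without a filter, the camera adjusted p was 0.940 for the miR-181 list and 0.472 for the epithelial list, in the other direction. Leaving out each library in turn gave −0.0864 to 0.300 (miR-140-5p), −0.0403 to 0.0621 (miR-30c-5p), −0.226 to 0.167 (miR-155-5p), −0.149 to 0.134 (miR-335-3p), −0.0146 to 0.207 (miR-128-3p), −0.0180 to 0.130 (miR-210-3p), −0.648 to 0.475 (miR-19b-3p), −0.0497 to 0.123 (let-7a-5p), −0.123 to 0.270 (miR-126a-5p) and −0.0684 to 0.0318 (miR-322-5p), and camera adjusted p of 0.681 to 0.974 (miR-181 list) and 0.626 to 0.877 (epithelial list).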

Other observations

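The tests of arm ratios and of the position of P0 replicate 3 were chosen only after those results were seen; the others were chosen before. Clusters and miRNAs named here were chosen after their values were seen.

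On chromosome X, 8 of 10 arms of the cluster of Mir500, Mir501, Mir362, Mir188 and Mir532 (7237683 to 7248497, GRCm38) fell, with miR-532-5p at a log2 fold change of −1.04 (SE 0.13) and miR-188-5p at −1.22 (SE 0.24). miR-378a-3p, which lies in the gene of the metabolic coactivator PGC-1beta, fell from 540 to 265 CPM (−1.03, SE 0.12), and miR-483-3p, from the imprinted Igf2 gene, from 175 to 80.7 CPM (−1.11, SE 0.14).

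Clusters were compared by hairpin means, the log2 fold changes averaged over a hairpin's arms, which hides opposite arms such as those of miR-181c. Over 36 clusters of 143 hairpins within 10 kb of each other, the SD of hairpin means within clusters was 0.295. It was 0.606 when cluster labels were shuffled (permutation p = 1e-04, the smallest that 10000 shuffles can give). Without the Dlk1-Dio3 and Sfmbt2 clusters the SD was 0.290 against 0.691 over 31 clusters (permutation p = 1e-04, again the smallest). The hypothesis that a shared transcript or shared control of a cluster sets part of these changes is consistent with this permutation p, but mature counts do not measure transcription.

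The fall of the Dlk1-Dio3 miRNAs was weighed against scaling and abundance. The list's median stayed at or below −0.439 under the other 4 scalings, so the fall did not depend on which of them was used. These scalings raised the log2 fold changes of all miRNAs by a median of at most 0.0266 against TMM. They could not have brought the list near 0, so a larger scaling error was not tested. The list's median lay at percentile 0 of 10000 lists of the same size matched on mean CPM. Medians of the matched lists ran from −0.324 to 0.231, which argues against the abundance of its members. For some hairpins the measured change differed between arms. The log2 ratio of 5p to 3p reads was higher at P2 for miR-376b (1.17), miR-540 (1.25), miR-433 (0.94), miR-369 (0.74) and miR-381 (0.78, minor arm at 0.657 CPM). Their limma adjusted p-values ran from 0.00307 to 0.0495, and the region's other tested hairpins did not pass. Lower activity of the region in passaged cells would not by itself shift these ratios. It stays open as an untested hypothesis for the fall, as does a change in which cells make up the culture.

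The ratio of 5p to 3p reads changed for 20 of 176 hairpins (limma, adjusted p under 0.05), while the 2 arms' log2 fold changes correlated at 0.741 across hairpins, which are not independent replicates. The 5p share rose for miR-15a (1.32, SE 0.18), miR-15b (0.99, SE 0.18) and miR-195a (1.26, SE 0.14), and fell for miR-181c (−1.81, SE 0.20), the 1 hairpin of 49 with both arms called whose arms went opposite ways. All 20 (100%) have 1 annotated locus and no near-identical partner, but so have 163 of the 176 hairpins (92.6%). Arms were paired by name, which nearly fixes that share, so reads shared between paralogs cannot be told apart from other causes. With both arms at 100 CPM or more, 1 of 24 hairpins changed (4.17%, miR-322), against 19 of 152 (12.5%) of the others, so an effect of few reads on the minor arm cannot be told apart from a change in arm use.

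P0 replicate 3 lay towards the P2 libraries by 0.211 of the distance between the groups, over 310 miRNAs, against −0.0621 to 0.0709 for the other 5 libraries. The total of this library ranks 2 of the 3 at P0. A middle rank among 3 totals can arise whatever the cause, so the rank does not decide on depth. The library's shift of only 0.211 over 310 miRNAs, not chosen on group differences, argues against a swap with a P2 library. The 20 miRNAs with the largest changes at 10 CPM or more implied a median share of P2 material of 0.142. They had been chosen with non-overlapping groups, which keeps that share below the level of a P2 library. It therefore cannot decide on a swap. P2 material mixed into the library has values on both sides: the implied shares ran from −0.197 to 0.366 with quartiles of 0.0559 and 0.183, close enough to their median to meet a first criterion for mixing set on the quartiles alone. Against mixing at the median share goes miR-204-5p, added to the criterion after that result, which implied 0.0173 and lay at 7.68 CPM where that share gives 20.9 CPM; miR-1247-5p and miR-145a-3p implied 0.00729 and −0.00625. These are values of single miRNAs in this library alone, so mixing, above all at a smaller share, was not excluded. Nor was it told apart from a culture further along the same change, which was not tested.

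For the 108 higher and 122 lower miRNAs, only 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave as many, and the highest of the others gave 0 and 0. Every other split mixes P0 and P2 libraries, which puts the group difference into the spread within groups. Its 0 calls are therefore not a level to expect by chance. For the 10 lists, it was also 1 of 10, but the other splits still gave 3 to 8 lists. Those splits keep part of the group difference, so 3 to 8 lists are not a level to expect by chance either. The 10 splits are too few for a share under 0.05.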
